A study of Arabidopsis thaliana with 36 samples.

How the data were processed

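Roots and shoots of seedlings in water or PEG+SHAM were profiled by MARS-seq in 36 libraries, 3 for each of 12 groups. The study's values came as 1 table of normalized signal, in which the authors had divided gene counts by 1 size factor per library and rounded the result to 0.1. The submitters' notes name bcl2fastq, cutadapt, STAR 2.4.2a, HTSeq and DESeq2 without saying what each was used for. The genome build, the annotation, the handling of molecular identifiers, the strandedness and any gene filter are not given in the sources used here, so no coordinates are printed. The table held 16283 genes and 36 libraries, and none of its columns was left out.

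Whole read counts were recovered from the deposited signal by searching, in each library, for the step of which its values are multiples. A value was called whole when it lay within the rounding of 0.05 of a multiple, and at least 99.994% of the values of every library did, out of 586188 values in the table. In 36 simulated libraries the search returned the step within 0.1% in 36, and 100% of the simulated counts. The recovered reads served for depth, edgeR and DESeq2, and the deposited normalized signal served for the main test. Of the gene identifiers, 16183 (99.39%) matched the reference annotation, which was used for symbols and for the genome of origin alone. It placed 74 genes on the chloroplast and 26 on the mitochondrial genome.

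The main test was limma 3.58.1 with a mean-variance trend on log2 of the normalized signal plus 1. Each tissue was fitted with 18 libraries and 6 group means, and comparisons between tissues were fitted with 36 libraries and 12 group means. Genes with a value of 5 or more in at least 3 libraries of the tissue were tested (in each tissue for the difference of the responses, in either tissue for the comparison of tissues). A Benjamini-Hochberg adjusted p under 0.05 was a call. PEG+SHAM libraries were compared with the water set whose titles carry the same prefix, PS0. Differences among the 3 water sets were tested with limma's moderated F. All fold changes are log2, given with their standard error from the fit, and group means of normalized counts are given with the SD of the replicates. The tests, the control, the filter, the gene lists and the rule for named genes were chosen before the data were examined. Alternatives added later are named as such in the closing section.

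Replicate numbers of different groups showed no clear pairing of the libraries. After removal of group means, libraries with the same number correlated across genes with a mean r of 0.041 in roots and 0.001 in shoots, over 45 pairs each. In roots 15 of these pairs had r over 0.1, in shoots 7, and single root pairs ranged from -0.472 to 0.51. The highest mean correlation was with libraries of the own number for 6 of 18 root and 8 of 18 shoot libraries. Root and shoot libraries of the same set and number had a mean r of -0.035. For 9 of 18 root libraries the closest shoot library of the set had the same number. The main fit, chosen beforehand, had no term for replicates, and a replicate block was run as an alternative.

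The named genes are, for each tissue and time against the PS0 water set, the 5 with the largest rise and the 5 with the largest fall among called genes with a mean of 20 or more in the higher group and with no overlap between treated and water libraries. The same rule was used for the other comparisons, without the overlap condition for the difference between tissues. Organelle genes and genes without an identity in the table were left out. Every member of a gene list could be named, and examples are those with the largest absolute moderated statistic at that time. Genes whose call was lost when 1 library was left out are mostly passed over as examples, a choice made after the data were examined.

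The 21 gene lists cover dehydration and abscisic acid response, type 2C phosphatases of abscisic acid signalling, aquaporins, photosynthesis (also the marker list for shoot tissue), root markers, heat shock, detoxification, lipoxygenase and jasmonate synthesis, jasmonate response, rapid oxidative stress, alternative respiration, nitrate response, ribosome biogenesis, ribosomal proteins, auxin response, cell wall growth, cell cycle, circadian clock, sugar starvation, salicylate response and reference genes. The root markers share 2 genes with the aquaporins, 1 with the nitrate and 1 with the auxin list. Lists with at least 5 tested members were tested with limma's camera at a preset correlation of 0.01 and again with an estimated correlation. At the preset correlation a median of 19 tests also passed after labels were reassigned within tissue. The preset adjusted p alone therefore does not secure a list. The adjusted p is over 120 tests of 20 lists for the 6 comparisons with the PS0 water set, over 60 for the differences between tissues, over 20 for each comparison of 3 h with 1 h or of all treated with all water libraries, and over 21 for root against shoot in water.

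To see what the test could find, counts were drawn anew for each library from the tissue mean and spread of each gene. Genes abundant in both tissues were altered by known folds. Apart from depth and the altered genes, simulated libraries of a tissue differed only by chance. Outlying libraries and other differences between water sets played no part. For roots at 3 h, limma called 9.0% of the genes altered 2-fold, 80.6% of those altered 4-fold and 98.5% of those altered 8-fold, with 6 false calls among 11555 genes. For the difference between tissues at 3 h it called 6.0%, 47.8% and 90.9%, with 7 false calls among 9031 genes. The counts of called genes, and the named genes where a setting tests them, were recomputed with other pseudocounts and filters, TMM and quantile normalization, edgeR, DESeq2, a minimum log2 change, a replicate block, fits of only the compared groups, a depth term, without groups of libraries and without each library in turn, and with other water sets as control for the comparisons that use PS0. The list tests against PS0 and between tissues were recomputed with other water sets as control, with a replicate block, without the shallow libraries and without each library in turn. Other tools were edgeR 4.0.16 and DESeq2 1.42.0 in R 4.3.3, with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.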

Results

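Wild-type Arabidopsis thaliana seedlings (Col-0, 7 d old) were held in water or in polyethylene glycol (PEG) with salicylhydroxamic acid (SHAM), an inhibitor of lipoxygenases and of the alternative oxidase. Transcripts of their roots and shoots were counted by MARS-seq, a sequencing method that reads the 3′ ends of transcripts. The sample labels give 30% PEG with 1 mM SHAM for 1, 2 or 3 h, an osmotic pressure of -2.0 MPa, 21 °C and 30 to 50 seedlings per biological replicate. The treatment protocol also names 0.1 mM SHAM, and the design text names a start at 0 h while the controls are labelled as 1 h in water. Each tissue had 3 treated groups and 3 water sets, called S0, PS0 and PH0 after their title prefixes, with 3 libraries in each of the 12 groups. Libraries of PEG alone, SHAM alone or PEG with histidine were not analysed here, so the effects of PEG and of SHAM cannot be separated. Water libraries of 2 h and 3 h were not used here either, so the later times are compared with water at 1 h.

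The 36 libraries held between 161684 and 7181461 recovered reads, with a median of 1668297. In kiloreads, root libraries ranged from 429.8 to 7181.5 and shoot libraries from 161.7 to 3622.4. Libraries under 600 kiloreads were root PS0 replicate 3 (521), root 1 h replicate 2 (429.8), shoot PS0 replicate 1 (512.6), shoot 2 h replicate 2 (340.2) and shoot PH0 replicate 1 (161.7).

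Root and shoot libraries in water carried the transcripts of their own tissue. AGP30, an arabinogalactan protein, averaged 224.9 ± 76.3 normalized counts in roots and 0.978 ± 2.53 in shoots (SD, n = 9 each; log2 difference 7.26 ± 0.33 SE). RBCS2B, a small subunit of Rubisco, averaged 12.7 ± 9.88 in roots and 15330.4 ± 9762.5 in shoots (-10.20 ± 0.42). How reads shared by such paralogs were counted is not given in the sources used here. Of 28 photosynthesis genes 28 were lower in roots, of 16 root markers 15 were higher, and of 11 ribosome biogenesis genes 11 were higher (camera adjusted p = 3.36e-31, 1.98e-07 and 6.26e-04, and 0.00997, 0.00187 and 0.0238 with an estimated correlation). Of 13218 genes limma called 6153 higher and 3010 lower in roots. The median log2 difference of all tested genes was 0.576, so this split goes with a shift of all genes. The photosynthesis genes summed to between 704.9 and 7003.4 normalized counts in the root libraries and to at least 155629 in the shoot libraries.

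The number of genes called between PEG+SHAM and the PS0 water set was larger at 3 h than at 1 h in both tissues. In roots 100 genes were higher and 99 lower at 1 h, 213 and 150 at 2 h, and 417 and 367 at 3 h, of 11950 tested. In shoots 68 were higher and 23 lower at 1 h, 456 and 529 at 2 h, and 697 and 771 at 3 h, of 10459 tested. For scale, the 3 water sets of 1 treatment label differed among themselves in 707 root and 2665 shoot genes by the moderated F. Each treated group was compared with 1 water set, so a difference between sets can enter these calls. The counts depend on the control and the fit. Against S0 and PH0 they were 2472, 1830 and 2877 at 1, 2 and 3 h in roots and 2009, 2857 and 3037 in shoots, against all 3 water sets 1953, 1374 and 2530 in roots and 1049, 2392 and 2613 in shoots, and with a depth term 1070, 589 and 1546 in roots, so the 2 h count in roots was then the lowest. The median log2 change of all genes in roots was -0.12, -0.10 and -0.16 at the successive times. Rescaling by TMM moved it by 0.14, 0.17 and 0.22 in roots and by 0.15, 0.08 and 0.11 in shoots, and quantile normalization by 0.13, 0.09 and 0.14 in roots.

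**Figure D1:**
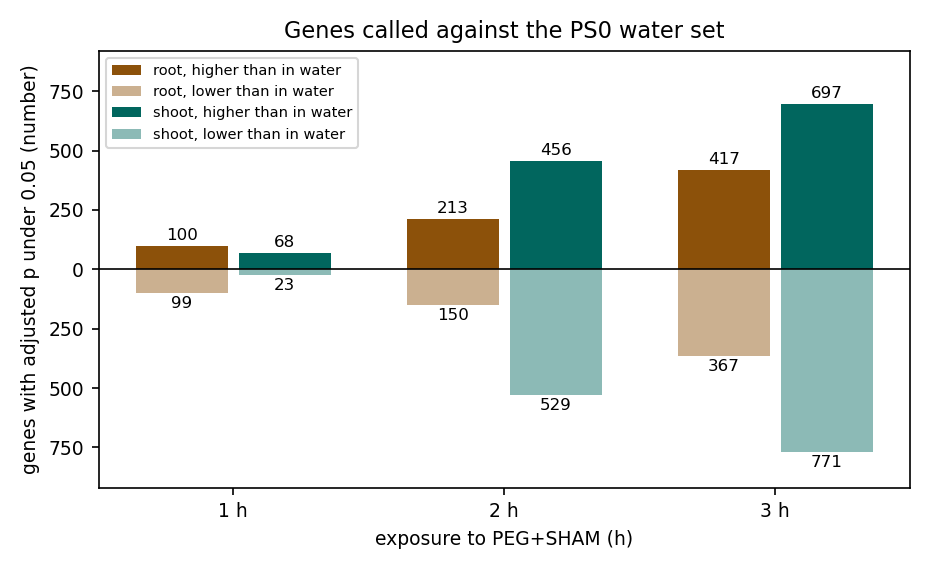
Number of genes called higher or lower by limma (y axis) after 1, 2 and 3 h in PEG+SHAM against the PS0 water set (x axis), for roots and shoots. Roots had 417 higher and 367 lower genes at 3 h, and shoots had 697 and 771.

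In roots at 1 h, NCED3 and PP2CA were among the genes already higher. NCED3, an enzyme that commits carotenoids to synthesis of abscisic acid (ABA), rose from 0.9 ± 1.56 normalized counts in water to 22.7 ± 17.8 (SD, n = 3; log2 change 3.69 ± 0.58 SE, adjusted p = 0.00458). PP2CA, a type 2C protein phosphatase (PP2C) that restrains ABA signalling, rose from 70.5 ± 9.03 to 294.6 ± 151.3 (1.94 ± 0.27, adjusted p = 0.00143). Of 8 PP2C genes it was the 1 that rose, or 2 with 1 lower adjusted over the list alone (camera adjusted p = 0.0455, and adjusted p = 0.179 with an estimated correlation). The list call was lost without PS0 replicate 2 (0.0935) or 3 (0.0745) or 1 h replicate 1 (0.0534), 2 (0.0614) or 3 (0.107). DREB2A, a transcription factor of the dehydration response, rose by 3.15 ± 0.68, and PPC3, a phosphoenolpyruvate carboxylase, fell from 33.2 ± 16.3 to 2.87 ± 3.07 (-3.43 ± 0.65). DREB2A missed the threshold without PS0 replicate 2 (adjusted p = 0.0871) or 1 h replicate 2 (0.0658), and PPC3 without PS0 replicate 2 (0.0525) or 3 (0.062). Of 21 rapid oxidative stress genes 1 rose, or 6 with 1 lower adjusted over the list alone, and camera placed the list higher (adjusted p = 4.42e-06, and adjusted p = 0.0952 with an estimated correlation). Of 25 dehydration and ABA response genes 2 rose, or 5 adjusted over the list alone (adjusted p = 0.00213, 0.151 without 1 h replicate 2, and adjusted p = 0.259 with an estimated correlation). Under TMM 4 of them rose, with edgeR 3 and with DESeq2 5. Photosynthesis genes were placed higher as a list while limma called 0 of 27 (3 at an unadjusted p under 0.05, and 0 with edgeR and with DESeq2; adjusted p = 0.00747, and adjusted p = 0.583 with an estimated correlation). They summed to 7003.4 normalized counts in 1 h replicate 2 against a root median of 1371.9, and without that library the list's direction reversed (adjusted p = 0.466). Of 16 root markers 2 fell, or 6 adjusted over the list alone, with adjusted p = 0.0228, and adjusted p = 0.145 with an estimated correlation. The root marker call was lost without the same library (0.178) or PS0 replicate 2 (0.0704). The number of calls at 1 h depends on single libraries. Without PS0 replicate 1, 2 or 3 the count of 199 became 364, 66 or 88, and without 1 h replicate 1 or 3 it became 410 or 125. A limma fit of the 6 compared libraries alone called 0 genes, with 848 at an unadjusted p under 0.05, where edgeR on them called 0 and, with all groups fitted, edgeR called 156 and DESeq2 398. The split of higher and lower genes was 141 and 76 under TMM, 90 and 47 under quantile normalization and 107 and 49 with edgeR.

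In roots at 2 h, MAPKKK18 and RAS1 were among the largest rises. MAPKKK18, an ABA-responsive protein kinase, rose from 4.43 ± 1.59 normalized counts to 135.8 ± 36.4 (SD, n = 3; log2 change 4.66 ± 0.39, adjusted p = 4.25e-06), and RAS1 from 5.97 ± 3 to 154.1 ± 44.2 (4.52 ± 0.46). UGT84A1, a glucosyltransferase of sinapate and related acids, fell from 91.4 ± 21.2 to 3.83 ± 2.1 (-4.33 ± 0.47, adjusted p = 3.45e-05), and the transcription factor gene RAP2.11 from 26.3 ± 11.6 to 1.77 ± 1.87 (-3.41 ± 0.54). Of 8 PP2C genes 5 rose, or 6 adjusted over the list alone, among them HAI1 (4.09 ± 0.50) and PP2CA (2.45 ± 0.27), with a camera adjusted p = 2.4e-10, and 0.00162 with an estimated correlation. Of 25 dehydration genes 9 rose, or 12 adjusted over the list alone, among them NCED3 (4.44 ± 0.58) and AFP1 (2.15 ± 0.34), with adjusted p = 1.67e-10, and 0.0452 with an estimated correlation. Of 16 root markers 3 fell, or 5 adjusted over the list alone, among them the root hair expansins EXPA7 (-2.50 ± 0.31) and EXPA18 (-2.27 ± 0.29), with adjusted p = 2.06e-04, and 0.0393 with an estimated correlation. Of 8 circadian clock genes PCL1 rose (1.27 ± 0.22), and 2 adjusted over the list alone (adjusted p = 0.00579, and 0.0452 with an estimated correlation). The 363 calls were 87 in a fit of the compared groups alone, 230 without PS0 replicate 2 and 234 or 236 without 2 h replicate 1 or 3, and TMM called 282 higher and 111 lower.

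In roots at 3 h, PP2C and dehydration genes rose. MAPKKK18 reached 421.4 ± 16.3 normalized counts against 4.43 ± 1.59 in water (SD, n = 3; log2 change 6.32 ± 0.39, adjusted p = 6.15e-08). AT3G02480, of the late embryogenesis abundant family, rose from 23.4 ± 21.2 to 1203.3 ± 371.7 (6.02 ± 0.81), AT3G03341 from 1.67 ± 1.24 to 269.7 ± 68 (6.73 ± 0.58) and TSPO, a membrane protein, from 0.9 ± 1.56 to 82.3 ± 11.8 (5.74 ± 0.70). UGT84A1 fell to 2.17 ± 1.42 (-4.93 ± 0.47, adjusted p = 2.92e-06). Of 25 dehydration genes 16 rose, or 17 adjusted over the list alone, among them AFP1 (3.83 ± 0.34), NCED3 (4.96 ± 0.58), the raffinose pathway gene GolS2 (5.61 ± 0.80) and the NAC transcription factor gene RD26 (2.41 ± 0.36). Of 8 PP2C genes 6 rose, or 7 adjusted over the list alone, among them HAI1 (from 4.8 ± 1.57 to 286 ± 27.7, 5.66 ± 0.50) and ABI1 (1.91 ± 0.23). Of 16 root markers 6 fell, or 7 adjusted over the list alone, among them EXPA18 (-2.90 ± 0.29), EXPA7 (-2.74 ± 0.31) and the Casparian strip gene CASP1 (-1.25 ± 0.22). The camera adjusted p was 1.11e-20 for dehydration, 7.17e-14 for PP2C and 3.92e-06 for root markers, and 0.00635, 4.52e-04 and 0.0118 with an estimated correlation. In water, 9 of the 25 dehydration genes were higher in PS0 roots than in the mean of S0 and PH0. The 784 calls were 458 in a fit of the compared groups alone, 520 without PS0 replicate 2 and 448 or 503 without 3 h replicate 2 or 3, and the split was 565 higher and 244 lower under TMM and 509 and 273 with edgeR.

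Heat shock, detoxification and rapid oxidative stress genes also rose in roots at 3 h, with list tests that were lost with an estimated correlation. Of 11 heat shock genes 5 rose, or 6 adjusted over the list alone, among them HSFB2A (2.87 ± 0.38, n = 3 per group) and HSP70 (3.45 ± 0.52), with a camera adjusted p = 3.56e-05, and adjusted p = 0.0952 with an estimated correlation. Of 22 detoxification genes 6 rose, or 7 with 1 lower adjusted over the list alone, among them the glucosyltransferase gene UGT75B1 (3.31 ± 0.50) and OPR1 (1.76 ± 0.31), with adjusted p = 0.00449, and adjusted p = 0.243 with an estimated correlation. Of 21 rapid oxidative stress genes 5 rose and 1 fell, or 9 and 1 adjusted over the list alone, among them CZF1 (from 165.4 ± 29.5 to 406.2 ± 26.5, SD), with adjusted p = 9.8e-05, and adjusted p = 0.14 with an estimated correlation. Of 8 circadian clock genes PCL1 (1.79 ± 0.22) and RVE1 (2.89 ± 0.58) rose, with adjusted p = 0.00997, and adjusted p = 0.0561 with an estimated correlation. Among 9 alternative respiration genes 2 rose, with adjusted p = 0.0377, 0.216 without PS0 replicate 3 and 0.0769 without 3 h replicate 1, and adjusted p = 0.177 with an estimated correlation. These included AOX1A, an alternative oxidase (from 73.9 ± 20.6 to 185.6 ± 41.4, SD, n = 3; 1.33 ± 0.36, adjusted p = 0.0304). Its adjusted p was 0.0926 or 0.0818 without PS0 replicate 1 or 3, and 0.127, 0.0725 or 0.0575 without 3 h replicate 1, 2 or 3.

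In the other lists limma called few genes in roots at 3 h. Of 14 auxin response genes 2 rose (4 with 1 lower adjusted over the list alone, 3 with edgeR and 4 with DESeq2; camera adjusted p = 0.0443, and adjusted p = 0.127 with an estimated correlation). The auxin call was lost without PS0 replicate 1 (0.0855) or 2 (0.0596) and without 3 h replicate 1 (0.0663) or 2 (0.0586). Of 11 ribosome biogenesis genes 1 rose, or 2 adjusted over the list alone (adjusted p = 0.0304, 0.113 without PS0 replicate 3 and 0.09 without 3 h replicate 1, and adjusted p = 0.132 with an estimated correlation). Of 14 jasmonate response genes only CYP94B3, which inactivates jasmonoyl-isoleucine, rose (2.21 ± 0.32, n = 3 per group; 4 with 1 lower adjusted over the list alone, 3 with edgeR and 4 with DESeq2), and the list did not pass (adjusted p = 0.0506). Of 20 cell wall growth genes 1 rose and 3 fell, or 1 and 4 adjusted over the list alone, among them XTH24 (-2.08 ± 0.43), and of 11 nitrate response genes 1 rose and 1 fell, or 1 and 3 adjusted over the list alone (adjusted p = 0.384 and 0.947). Of 10 reference genes 1 fell, or 1 rose and 1 fell adjusted over the list alone (adjusted p = 0.89). Limma called 0 of 27 photosynthesis, 0 of 13 lipoxygenase and jasmonate synthesis, 0 of 12 cell cycle, 0 of 24 ribosomal protein and 0 of 13 sugar starvation genes. At an unadjusted p under 0.05 it called 1, 2, 0, 0 and 3 of these, and edgeR and DESeq2 called 0 of each. For the nitrate, cell cycle, reference and ribosomal protein lists, which did not pass, median and mean lay below 0 while camera placed them higher relative to the other genes.

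Between 1 h and 3 h in PEG+SHAM, a comparison that uses no water library, PP2C and dehydration genes rose in roots. HAI2, a PP2C, went from 1.4 ± 1.45 to 82.7 ± 38.4 normalized counts (SD, n = 3; log2 change 5.19 ± 0.54, adjusted p = 3.92e-05), and AT3G02480 from 58.3 ± 61.9 to 1203.3 ± 371.7 (4.94 ± 0.81). The paralogs AT4G12510 and AT4G12520 fell by 1.76 ± 0.28 and 1.72 ± 0.27. Of 8 PP2C genes 5 rose (7 adjusted over the list alone), of 25 dehydration genes 7 (15) and of 11 heat shock genes 3 (6), HSP70 among them (3.82 ± 0.52). Their camera adjusted p was 5.26e-19, 9.06e-22 and 3.63e-10, and 6.4e-05, 0.00455 and 0.0113 with an estimated correlation. Of 16 root markers 2 fell (6), with adjusted p = 1.16e-05, and 0.0113 with an estimated correlation. In total 120 genes rose and 32 fell. The 152 calls were 15 in a fit of the compared groups alone, 97 or 252 without 1 h replicate 1 or 2 and 87 or 83 without 3 h replicate 1 or 2, and the split was 139 and 12 under TMM and 206 and 101 with DESeq2.

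Over all 9 treated against all 9 water libraries of roots, RAS1 averaged 138.4 ± 96.5 against 3.5 ± 2.45 normalized counts (SD, n = 9; log2 difference 4.64 ± 0.27, adjusted p = 1.68e-09). Genes that fell included AT3G49960, from 37.2 ± 32.9 to 1.01 ± 1.71 (-4.10 ± 0.37), and UGT84A1 (-3.85 ± 0.27), and XTH12, a xyloglucan-modifying enzyme, fell from 56.9 ± 38.4 to 4.86 ± 4.88 (-3.28 ± 0.24). Of 25 dehydration genes 21 rose (22 adjusted over the list alone), LTI78 among them (2.88 ± 0.17). Of 14 jasmonate response genes 7 rose and 1 fell (7 and 1 adjusted over the list alone), CYP94B3 among them (1.82 ± 0.18), and of 13 sugar starvation genes 7 rose and 1 fell (10 and 1), the asparagine synthetase gene ASN1 among them (2.38 ± 0.16). Of 16 root markers 1 rose and 8 fell (1 and 8). Camera placed these 4 lists apart, with adjusted p = 1.1e-20, 2.4e-05, 4.7e-06 and 4.78e-04, and 0.00561, 0.0363, 0.0388 and 0.0387 with an estimated correlation. Of 8 PP2C genes 6 rose (6), with adjusted p = 4.79e-08, and 0.0045 with an estimated correlation. Differences between sets enter this comparison, since the treated libraries share a title prefix with PS0 alone. The SE and limma p rest on the spread of libraries within groups, not on that between sets. In water, PS0 roots had 9 dehydration, 3 jasmonate response and 3 sugar starvation genes higher than the mean of S0 and PH0. In each of these lists 0 were lower. ASN1 averaged 356.4 ± 111.5 in PS0 roots, against 48.7 ± 12.9 in S0 and 105.7 ± 21.3 in PH0. Against PS0 at 3 h limma called 1 jasmonate response and 0 sugar starvation genes. In total 1191 genes were higher and 2894 lower, against 1825 and 2132 under TMM, 1809 and 1675 under quantile normalization, 2051 and 2132 with edgeR and 1714 and 2598 with DESeq2.

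In shoots at 1 h, ERF53, NCED3 and PP2C genes rose and PYL6 fell. ERF53, an AP2/ERF transcription factor, rose from 2.93 ± 0.666 to 110.2 ± 39.8 normalized counts (SD, n = 3; log2 change 4.77 ± 0.32, adjusted p = 6.12e-08), and NCED3 from 1.77 ± 1.59 to 34.6 ± 12.4 (3.85 ± 0.62). PYL6, an ABA receptor, fell from 466.1 ± 106.1 to 67.8 ± 20 (-2.77 ± 0.29, adjusted p = 1.09e-05), and EXO, a gene of brassinosteroid-promoted growth, from 462.9 ± 46.8 to 106.5 ± 10 (-2.11 ± 0.34). Of 7 PP2C genes ABI1 (2.06 ± 0.20) and PP2CA (2.98 ± 0.31) rose, and 6 adjusted over the list alone (camera adjusted p = 5.31e-15, and 1.35e-04 with an estimated correlation). Of 28 dehydration genes 5 rose, or 9 adjusted over the list alone, among them RD26 (2.74 ± 0.26) and ERD10, a dehydrin (1.73 ± 0.26), with adjusted p = 1.91e-13, and 0.0452 with an estimated correlation. Of 15 detoxification genes UGT75B1 rose (1.74 ± 0.27), and 5 adjusted over the list alone (adjusted p = 1.38e-04, and 0.00795 with an estimated correlation). With DESeq2 5 PP2C and 8 dehydration genes rose. The 91 calls were 37 in a fit of the compared groups alone, 51, 58 or 139 without PS0 replicate 1, 2 or 3 and 55, 33 or 28 without 1 h replicate 1, 2 or 3. The split was 106 higher and 17 lower under TMM and 131 and 73 with DESeq2.

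In shoots at 2 h, aquaporin genes rose along with dehydration and PP2C genes. RD28, a plasma membrane aquaporin, rose from 44.8 ± 10.8 to 1110.3 ± 155.5 normalized counts (SD, n = 3; log2 change 4.62 ± 0.27, adjusted p = 1.21e-09), and ERF53 reached 614.9 ± 32.8 (7.30 ± 0.32). PYL6 fell to 25.7 ± 10.4 (-4.17 ± 0.29) and BRS1, a serine carboxypeptidase gene, from 45.7 ± 6.07 to 1.53 ± 2.66 (-4.71 ± 0.58). Of 19 aquaporins 11 rose and 1 fell, or 11 and 3 adjusted over the list alone, PIP2A (2.87 ± 0.18) and TIP2;2 (2.67 ± 0.22) among the risers. Of 28 dehydration genes 23 rose, or 26 adjusted over the list alone, and of 7 PP2C genes 7 rose, also adjusted over the list alone. Camera gave adjusted p = 6.37e-09 for aquaporins, 4.56e-36 for dehydration and 3.27e-15 for PP2C, and 0.0393, 0.0024 and 1.35e-04 with an estimated correlation. Of 15 detoxification genes 6 rose, or 7 adjusted over the list alone, UGT75B1 among them (4.08 ± 0.27), with adjusted p = 5.69e-06, and 0.00296 with an estimated correlation. Of 28 photosynthesis genes 9 fell, or 19 adjusted over the list alone, among them LHCB2.2 (-1.63 ± 0.22), with adjusted p = 4.9e-08, and adjusted p = 0.0607 with an estimated correlation. Quantile normalization called 5 of them and DESeq2 17. The 985 calls were 427 in a fit of the compared groups alone, 624, 636 or 1618 without PS0 replicate 1, 2 or 3.

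In shoots at 3 h, nearly every tested dehydration gene was higher. AT4G28140, an AP2/ERF transcription factor, reached 828 ± 215.3 normalized counts against 0.867 ± 0.777 in water (SD, n = 3; log2 change 8.86 ± 0.43, adjusted p = 6.02e-11), TSPO 415.5 ± 121.5 (8.18 ± 0.61) and MAPKKK18 482.5 ± 101.7 (7.99 ± 0.58). IPT3, an enzyme of cytokinin synthesis, fell from 55.8 ± 16 to 0.433 ± 0.751 (-5.38 ± 0.43), PYL6 to 20.8 ± 6.63 (-4.44 ± 0.29) and FLA9, a fasciclin-like arabinogalactan protein, from 376.2 ± 103.5 to 22.5 ± 9.39 (-4.05 ± 0.24). Of 28 dehydration genes 26 rose, or 27 adjusted over the list alone, among them RD26 (4.76 ± 0.26), ERD10 (4.61 ± 0.26) and RD20, a caleosin (5.98 ± 0.40). Of 7 PP2C genes 7 rose, also adjusted over the list alone, ABI1 from 263.3 ± 26.7 to 2986.3 ± 139.4 (adjusted p = 2.59e-10). Of 19 aquaporins 12 rose and 2 fell, or 12 and 3 adjusted over the list alone, PIP2A from 333.6 ± 77.7 to 4069.5 ± 233.5 (3.63 ± 0.18) and RD28 by 5.25 ± 0.27. Of 15 detoxification genes 7 rose, or 8 adjusted over the list alone, among them UGT75B1 (4.72 ± 0.27) and GSTU7 (2.58 ± 0.35). The camera adjusted p was 5.26e-40 for dehydration, 2.59e-15 for PP2C, 8.1e-10 for aquaporins and 1.19e-05 for detoxification, and 0.0017, 1.35e-04, 0.0323 and 0.00348 with an estimated correlation. In water, PS0 shoots differed from the mean of S0 and PH0 in 12 of the 28 dehydration genes (11 higher, 1 lower) and in 9 of the 19 aquaporins (lower). The 1468 calls were 931 without 3 h replicate 3, and TMM called 787 higher and 571 lower.

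Photosynthesis and nitrate response genes fell in shoots at 3 h. Of 28 photosynthesis genes 16 fell, or 22 adjusted over the list alone, among them LHCB2.2 (from 538.5 ± 58 to 155.2 ± 6.51, SD, n = 3; -1.78 ± 0.22) and the Rubisco activase gene RCA (-1.02 ± 0.15), with a camera adjusted p = 2.08e-08, and adjusted p = 0.0591 with an estimated correlation. TMM called 11 of them and quantile normalization 10. In water, 12 of the 28 were lower and 3 higher in PS0 shoots than in the mean of S0 and PH0, and 2 of the 11 nitrate response genes were higher (adjusted p = 0.0154 and 0.00185, and adjusted p = 0.455 and 0.0852 with an estimated correlation). Of 11 nitrate response genes 4 fell, also adjusted over the list alone. They were the nitrate transporter gene NRT1.1 (from 921.1 ± 191.8 to 149 ± 8.44, -2.60 ± 0.19) and the transcription factor genes LBD39 (-1.35 ± 0.24), LBD38 (-0.86 ± 0.17) and LBD37 (-0.90 ± 0.22), with adjusted p = 0.00122, and adjusted p = 0.0591 with an estimated correlation. Of 15 lipoxygenase and jasmonate synthesis genes 6 rose, also adjusted over the list alone, among them JAR1, which joins jasmonate to isoleucine (3.31 ± 0.59), and the cyclase gene AOC3 (2.09 ± 0.40), with adjusted p = 0.0119, and adjusted p = 0.127 with an estimated correlation. Of 9 heat shock genes 4 rose, or 5 adjusted over the list alone, HSP70 among them (2.36 ± 0.32), with adjusted p = 0.0307, 0.149 without PS0 replicate 3, and adjusted p = 0.202 with an estimated correlation. Of 12 root markers 1 rose and 2 fell, or 1 and 3 adjusted over the list alone, with adjusted p = 0.0491, and adjusted p = 0.243 with an estimated correlation. EdgeR and DESeq2 each called 1 of them higher and 4 lower. The root marker call was lost without PS0 replicate 1 (0.0684) or 2 (0.0873) and without 3 h replicate 1 (0.0821) or 2 (0.0506).

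Other lists did not pass as lists in shoots at 3 h, with camera adjusted p of at least 0.131. Of 20 cell wall growth genes 2 rose and 5 fell, also adjusted over the list alone, among them the expansin EXPA10 (from 61.3 ± 3.17 to 1432.2 ± 2.21, SD, n = 3; 4.52 ± 0.27) and XTH24 (-2.18 ± 0.33). Of 12 sugar starvation genes 2 rose and 2 fell, or 3 and 3 adjusted over the list alone, among them TPS8 (3.40 ± 0.78) and the proline dehydrogenase gene ERD5 (-1.69 ± 0.18). Of 18 rapid oxidative stress genes 3 rose and 1 fell, or 5 and 1, CZF1 among them (1.46 ± 0.26), and of 14 jasmonate response genes 2 rose and 1 fell, or 3 and 1. Of 11 ribosome biogenesis genes 3 fell, also adjusted over the list alone, FIB2 among them (-1.48 ± 0.31), and of 10 auxin response genes 1 rose and 2 fell, also adjusted over the list alone, the auxin efflux gene PIN7 among them (-0.92 ± 0.18). Of 7 alternative respiration genes 1 rose (1 adjusted over the list alone), of 8 reference genes 1 rose (1) and of 24 ribosomal protein genes 1 fell (0). EdgeR and DESeq2 each called 3 alternative respiration genes higher. They called 2 and 1 reference genes higher and 0 and 2 ribosomal protein genes lower. Against S0 and PH0 in place of PS0, the ribosome biogenesis and ribosomal protein lists reversed direction (adjusted p = 0.00328 and 0.0161). In water, 8 of the 11 ribosome biogenesis genes and 12 of the 24 ribosomal protein genes were higher in PS0 shoots than in the mean of S0 and PH0 (adjusted p = 7.04e-08 and 2.1e-06, and adjusted p = 0.029 and 0.165 with an estimated correlation). Limma called 0 of 9 circadian clock and 0 of 5 cell cycle genes. At an unadjusted p under 0.05 it called 2 and 1 of these, edgeR called 1 and 0, and DESeq2 2 and 0. The auxin, circadian, reference and sugar lists had a median, mean and camera direction that differed in sign. The salicylate response list had 4 tested genes in roots and 3 in shoots, too few for a list test, and limma called 0 in either tissue at 3 h, also at an unadjusted p under 0.05, as did edgeR and DESeq2.

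**Figure D2:**
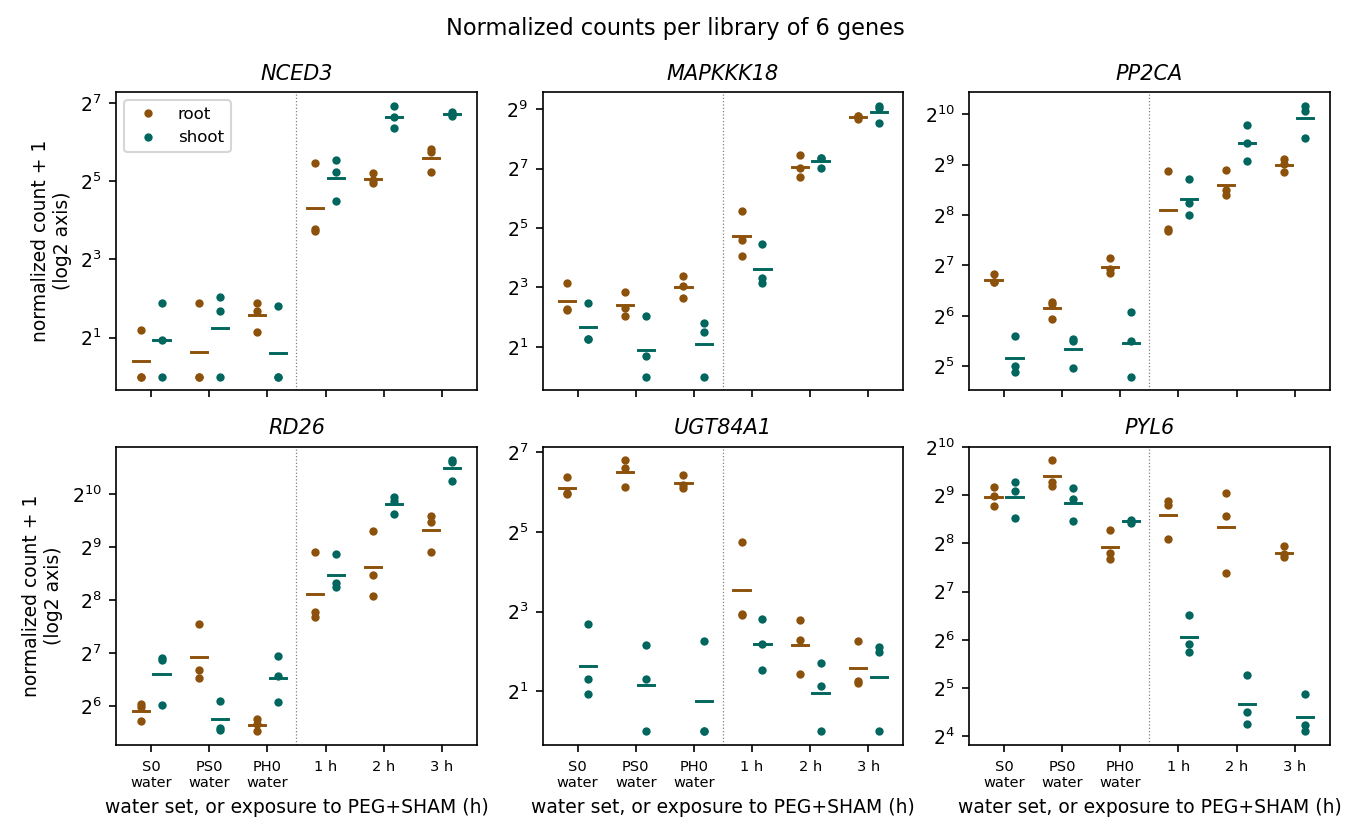
Normalized counts plus 1 per library on a log2 axis (y) of NCED3, MAPKKK18, PP2CA, RD26, UGT84A1 and PYL6 in the 3 water sets and at 1, 2 and 3 h in PEG+SHAM (x), in roots and shoots; each point is a library and bars are means on the log scale. MAPKKK18 averaged 4.43 in PS0 roots and 421.4 at 3 h, and PYL6 averaged 466.1 in PS0 shoots and 20.8 at 3 h.

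Between 1 h and 3 h in PEG+SHAM, dehydration, PP2C and aquaporin genes rose in shoots while nitrate and photosynthesis genes fell. RD20 went from 22 ± 3.52 to 1051.8 ± 233.7 normalized counts (SD, n = 3; log2 change 5.50 ± 0.40, adjusted p = 4.26e-08) and LEA7, a late embryogenesis abundant protein, from 2.37 ± 1.44 to 177.3 ± 53 (5.76 ± 0.59). IPT3 fell from 39.8 ± 4.34 to 0.433 ± 0.751 (-4.94 ± 0.43, adjusted p = 3.55e-07). Of 28 dehydration genes 22 rose (26 adjusted over the list alone), of 7 PP2C genes 7 (7), and of 19 aquaporins 11 rose and 1 fell (12 and 2). Of 11 nitrate response genes 4 fell (6), and of 28 photosynthesis genes 7 fell (10), LHCB2.2 by 2.13 ± 0.22. The camera adjusted p was 5.51e-47, 9.38e-14, 1.1e-16, 1.16e-06 and 1.19e-08 in that order, and 4.36e-04, 1.28e-04, 0.00306, 0.00511 and 0.0338 with an estimated correlation. Of 15 detoxification genes 3 rose (6 with 1 lower), with adjusted p = 3.04e-04, and 0.00511 with an estimated correlation. In total 312 genes rose and 341 fell. The 653 calls were 1337 in a fit of the compared groups alone, 430, 407 or 401 without 1 h replicate 1, 2 or 3 and 396 or 390 without 3 h replicate 1 or 3.

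Over all 9 treated against all 9 water libraries of shoots, ERF53 averaged 510.5 ± 324.2 against 0.978 ± 1.5 normalized counts (SD, n = 9; log2 difference 7.89 ± 0.19, adjusted p = 2.19e-16), and PUB19, a U-box ubiquitin ligase, 679.4 ± 603.5 against 4.5 ± 4.8 (6.76 ± 0.29). The ABA receptor genes PYL6 (from 441.7 ± 109.2 to 38.1 ± 25.3, -3.70 ± 0.17) and PYL4 (from 596.8 ± 191.5 to 90.9 ± 77.7, -3.08 ± 0.14) fell. Of 28 dehydration genes 28 rose, and of 14 jasmonate response genes 11 and of 15 lipoxygenase and jasmonate synthesis genes 10, with the same counts adjusted over the list alone. Of 28 photosynthesis genes 20 fell and 1 rose (22 and 2 adjusted over the list alone), RCA (-1.14 ± 0.09) among the fallers and CAB2 (1.98 ± 0.18) the riser. Camera gave adjusted p = 1.27e-34, 6.31e-05, 6.31e-05 and 3.1e-08 for these lists, and 0.00137, 0.00709, 0.0152 and 0.0375 with an estimated correlation. Of 7 PP2C genes 7 rose (7) and of 15 detoxification genes 8 (10), with adjusted p = 8.48e-12 and 4.5e-06, and 2.65e-04 and 0.00137 with an estimated correlation. Differences between sets enter here too, and the SE and limma p rest on the spread of libraries within groups alone. In water, PS0 shoots had 11 dehydration genes higher and 1 lower than the mean of S0 and PH0. For jasmonate response it was 3 and 0 (camera adjusted p = 0.00237, and 0.0598 with an estimated correlation). For lipoxygenase and jasmonate synthesis it was 2 and 1, and for photosynthesis 3 and 12. CAB2 averaged 21875.4 ± 9874.2 in PS0 shoots, against 4007.7 ± 1164.6 in S0 and 380.5 ± 76.3 in PH0. Against PS0 limma called 0 photosynthesis genes higher at 1, 2 or 3 h, also at an unadjusted p under 0.05. The rise of CAB2 is therefore not seen against PS0. Against PS0 at 3 h limma called 2 jasmonate response genes higher and 1 lower, and 6 lipoxygenase and jasmonate synthesis genes higher. In total 1425 genes were higher and 2163 lower, against 2072 and 1615 under TMM and 2013 and 1885 with edgeR.

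The responses of roots and shoots at 3 h differed in the aquaporins. The response of PIP2B was lower in roots than in shoots by 4.33 ± 0.28 (log2, SE, n = 3 libraries in each of 4 groups; limma adjusted p = 4.07e-12), and that of TIP2;2, a tonoplast aquaporin, by 4.97 ± 0.39. RD28 averaged 337.7 ± 92.8 in root water and 384.2 ± 78.1 at 3 h (SD, n = 3), against 44.8 ± 10.8 and 1720.9 ± 298.6 in shoots, a difference of -5.05 ± 0.40. Of 19 aquaporins 10 had a lower root response, or 12 adjusted over the list alone (camera adjusted p = 7.68e-19, and 6.01e-04 with an estimated correlation). Within roots 1 aquaporin rose and 4 fell, or 1 and 7 adjusted over the list alone, among them PIP2;4 (-2.12 ± 0.29), which is also on the root marker list, TIP4;1 (-1.58 ± 0.24) and PIP1;4 (1.63 ± 0.25). The root list passed with adjusted p = 0.0424, and adjusted p = 0.508 with an estimated correlation. Its call was lost without PS0 replicate 1 (0.0517), 2 (0.0517) or 3 (0.0913) or 3 h replicate 1 (0.149).

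**Figure D3:**
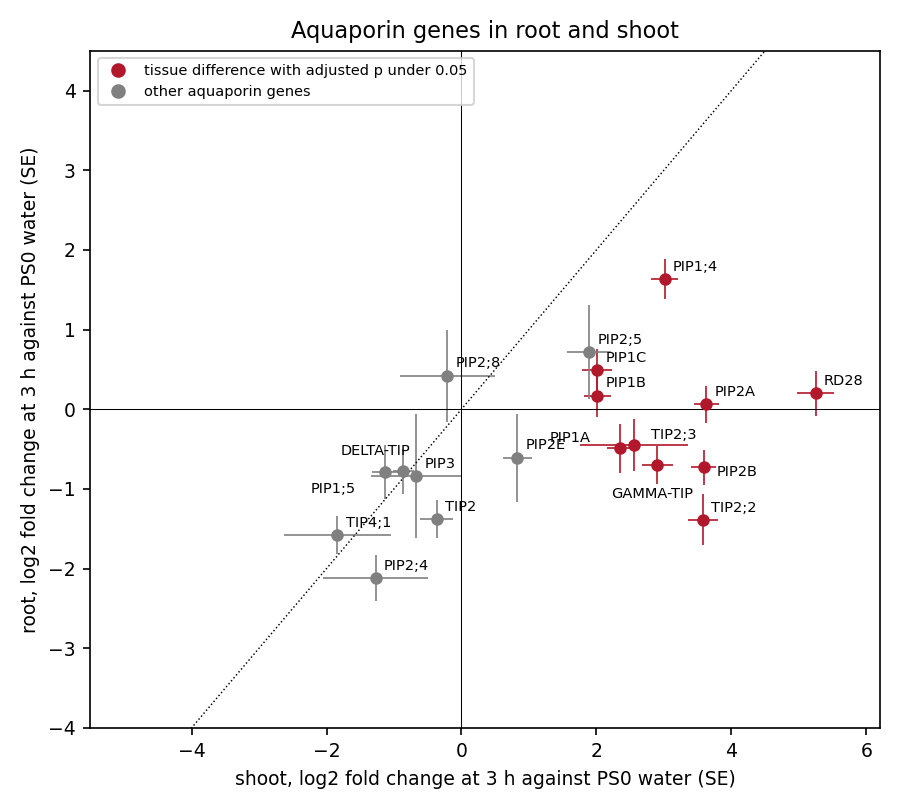
Log2 change of 19 aquaporins at 3 h in PEG+SHAM against the PS0 water set in shoots (x) and roots (y), with standard errors as bars, n = 3 libraries per group; the dotted line marks equal change and red points are the 10 genes with a called difference between tissues. PIP2A rose by 3.63 in shoots, and PIP2;4 fell by 2.12 in roots.

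Other groups also responded differently at 3 h. The response of ABI1 was lower in roots by 1.59 ± 0.30 (log2, SE, n = 3 libraries in each of 4 groups; adjusted p = 0.00109), that of ERD10 by 2.79 ± 0.44 and that of ABF3, an ABA-responsive transcription factor, by 2.31 ± 0.36. Of 7 PP2C genes 4 and of 25 dehydration genes 9 were lower, or 5 and 14 adjusted over the list alone (camera adjusted p = 1.08e-05 and 2.48e-14, and 8.41e-04 and 0.00998 with an estimated correlation). LHCB2.3, of the light-harvesting complex, rose from 54.7 ± 22.4 to 235.5 ± 58 in roots and fell from 734.1 ± 237.1 to 141.6 ± 30 in shoots (SD, n = 3; difference 4.46 ± 0.42, adjusted p = 1.2e-08). LBD39 was higher in the root response by 2.27 ± 0.36. In total 201 genes were higher and 151 lower in the root response, of 9191 tested, against 179 and 77 under TMM and 310 and 136 with edgeR. At 2 h it was 139 and 103 (135 and 46 under TMM, 204 and 95 with edgeR), with 157 calls in place of 242 without root 2 h replicate 1 and 99 in a fit of the compared groups alone. At 1 h it was 20 and 12 (20 and 21 under quantile normalization), ABI1 among the lower (-1.82 ± 0.30, adjusted p = 0.00115), with 3 calls in a fit of the compared groups alone, 19 without root PS0 replicate 1, 69 without root 1 h replicate 2, and 18 or 20 without shoot 1 h replicate 2 or 3. TMM moved the median difference of all genes by -0.09, 0.23 and 0.15 at the successive times.

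Genes called in both tissues moved mostly the same way, by limma calls among the 9191 genes tested in both, which share no library. At 3 h, 193 genes were higher in both tissues, where 26 would be shared by independent sets, and 54 lower in both, where 16.3 would be. The numbers at 2 h were 84 (8.8) and 16 (4.2), and at 1 h 12 (0.6) and 1 (0.1). At 3 h, 13 of 378 genes higher in roots and 4 of 220 genes lower in roots were called the opposite way in shoots. Both tissues were compared with PS0, so a shift of that set common to both tissues enters both calls. In water, 9 of 25 dehydration genes were higher in PS0 roots, and 11 of 28 higher and 1 lower in PS0 shoots. The numbers for independent sets also take every gene as equally likely to be called.

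The 3 water sets, which have 1 treatment label, differed from each other. LTI30, a dehydrin, averaged 299.2 ± 78.5, 1732.6 ± 857.4 and 186.6 ± 12 normalized counts in S0, PS0 and PH0 roots (SD, n = 3; adjusted p = 2.42e-04), and 43.2 ± 5.46, 245.8 ± 95.2 and 26.5 ± 6.9 in shoots (2.82e-06). CAB2, of the light-harvesting complex, averaged 4007.7 ± 1164.6, 21875.4 ± 9874.2 and 380.5 ± 76.3 in shoots. Relative to the mean of S0 and PH0, 9 of 25 dehydration genes were higher in PS0 roots, and 11 of 28 higher and 1 lower in PS0 shoots (camera adjusted p = 6.58e-11 and 1.64e-07, and adjusted p = 0.0598 and 0.165 with an estimated correlation). Limma called 707 of 11950 genes in roots and 2665 of 10459 in shoots. The root count was 2890 in a fit of the water sets alone, 309, 237 or 290 without S0 replicate 1, 2 or 3 and 340, 287 or 301 without PH0 replicate 1, 2 or 3, and the shoot count was 1089 in such a fit and 1551 or 1632 without S0 replicate 1 or 2. Against S0 and PH0 in place of PS0, treated roots at 3 h had 2877 called genes, of which 676 were also called against PS0, and treated shoots had 3037, of which 1103 were.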

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

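Of the tests here, the counts of other splits of the samples and the aquaporin test against the S0 and PH0 water sets were chosen only after the results were seen.

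The response to PEG+SHAM differed between roots and shoots, tested as the difference itself by limma, for 32 genes at 1 h, 242 at 2 h and 352 at 3 h. In 100 splits of the 12 libraries within tissue, 11, 8 and 3 gave as many as the real count at 1 h, 2 h and 3 h, with 989, 1008 and 583 in the highest other. Of the larger splits 9, 5 and 2 swap most labels in 1 tissue, which turns its response around, so these counts carry the response common to both tissues and decide nothing on a difference. That response was then estimated with the real labels and taken out of the libraries. Of the same 100 splits, 3, 3 and 1 then gave as many as the real 32, 242 and 352. The highest others were 1306, 1156 and 16. By the 5% rule a chance assignment of single libraries can be excluded at 3 h. Each group is 1 set of libraries, so these splits cannot exclude a difference between sets. At 1 h and 2 h the shares lie under 5% as well. Splits with 1306 and 1156 genes, several times the real count, point to a structure of the samples there, which was not tested further. Chance is therefore not excluded at 1 h and 2 h. At 1 h both larger splits again swap most labels in 1 tissue, and at 2 h 0 do. The response also differed between 3 h and 1 h, for 152 genes in roots and 653 in shoots. The 10 splits of 6 libraries are too few for a share under 0.05, with 1 of 10 at the real 152 and 33 in the highest other, and 1 of 10 at the real 653 and 0 in the highest other.

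Camera placed aquaporins lower in the root than in the shoot response at each time, with 0, 9 and 10 of 19 genes called at 1, 2 and 3 h and camera adjusted p = 0.00811, 1.69e-16 and 7.68e-19 (0.326, 9.03e-04 and 6.01e-04 with an estimated correlation). The authors' normalization was argued against by at least 8 of the 19 genes being called lower at 3 h under TMM, quantile normalization, edgeR and DESeq2, and library depth by 11 called with depth as a term. Reads assigned to the wrong paralog within a family were argued against by sums over the PIP1, PIP2 and TIP families. The sums were lower by 1.89 ± 0.35, 3.14 ± 0.29 and 1.97 ± 0.34 (log2, SE, n = 3 per group), the nearest to 0 at -5.4 SE. Reads shared between families, or left out of the counts because they were shared, would escape these sums and stay open. The choice of control was argued against for 3 h alone, by 10 called lower at 3 h against the S0 and PH0 water sets. A biological difference between the tissues, which the design names, stays open as an explanation too and was not itself tested.

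At 1 h the limma count of aquaporins with a lower root response was 0, or 3 adjusted over the list alone, with 4 at an unadjusted p under 0.05, 0 with edgeR and 3 with DESeq2. The list call was lost without shoot PS0 replicate 3 (0.182) or shoot 1 h replicate 3 (0.063), and the list's direction reversed against S0 and PH0 (0.983). Of 7 PP2C genes 2, 4 and 4 had a lower root response at 1, 2 and 3 h, with adjusted p = 3.57e-06, 2.5e-06 and 1.08e-05 (6.01e-04, 6.01e-04 and 8.41e-04 with an estimated correlation). Of 25 dehydration genes 8 and 9 were lower in the root response at 2 h and 3 h (5 under TMM at 2 h), with adjusted p = 2.91e-16 and 2.48e-14 (0.00602 and 0.00998 with an estimated correlation), and of 14 detoxification genes 1 at 2 h, with adjusted p = 9.89e-04 (0.0145 with an estimated correlation). At 1 h the dehydration list, with 0 of 25 genes called (2 lower adjusted over the list alone, 8 lower and 1 higher at an unadjusted p under 0.05, and 0 with edgeR and with DESeq2), was placed lower, and this call (adjusted p = 0.021, and adjusted p = 0.482 with an estimated correlation) was lost without root PS0 replicate 3 (0.231), shoot PS0 replicate 3 (0.324), root 1 h replicate 1 (0.165) or 3 (0.179) or shoot 1 h replicate 3 (0.207).

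Camera placed photosynthesis genes higher in the root response at 1 h, with 0 of 27 genes called (2 at an unadjusted p under 0.05, and 0 with edgeR and with DESeq2), adjusted p = 4.61e-04, and adjusted p = 0.482 with an estimated correlation, and the direction reversed without root 1 h replicate 2 (0.76). Of 18 rapid oxidative stress genes 1 was higher at 1 h, with a list adjusted p = 0.0114, and adjusted p = 0.482 with an estimated correlation, and lost the call without root PS0 replicate 1 (0.097), shoot PS0 replicate 2 (0.0752) or 3 (0.379) or root 1 h replicate 2 (0.114). Sugar starvation genes were placed higher at 1 h, with 0 of 12 genes called (2 at an unadjusted p under 0.05, 0 with edgeR and 1 with DESeq2), adjusted p = 0.0374, and adjusted p = 0.352 with an estimated correlation. The list lost the call without root PS0 replicate 2 (0.106), shoot PS0 replicate 1 (0.118) or 3 (0.157), root 1 h replicate 1 (0.0928) or 3 (0.218) or shoot 1 h replicate 3 (0.201). At 3 h 1 of 9 heat shock genes was higher in the root response, with a list adjusted p = 0.0299, and adjusted p = 0.326 with an estimated correlation. The list call was lost without root PS0 replicate 1 (0.111) or 3 (0.0842), shoot PS0 replicate 1 (0.0517) or 2 (0.0703) or root 3 h replicate 1 (0.0691). Of 11 nitrate response genes 3 and of 11 ribosome biogenesis genes 1 were higher at 3 h, with list adjusted p = 0.0114 and 0.0123, and adjusted p = 0.133 and 0.12 with an estimated correlation, and the nitrate call was lost without shoot PS0 replicate 3 (0.0646). Against S0 and PH0 both lists reversed direction (adjusted p = 0.77 for nitrate response and 0.0028 for ribosome biogenesis), and against all 3 water sets ribosome biogenesis did (0.316).

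Among single genes at 3 h, the response was higher in roots than in shoots by 5.98 for AT1G75960, 4.55 for AT2G34510, 4.46 for LHCB2.3, 4.04 for AT4G15700 and 4.04 for AT4G25780 (log2). AT1G75960 rose from 3.47 ± 1.68 to 44.6 ± 4.72 normalized counts in roots and fell from 101.4 ± 18.6 to 17.3 ± 8.33 in shoots (SD, n = 3). AT4G15700 lost its call without shoot PS0 replicate 1 (adjusted p = 0.0531) or 2 (0.051) or root 3 h replicate 3 (0.0546), and AT4G25780 without root PS0 replicate 1 (0.0634) or shoot 3 h replicate 2 (0.0607). The response was lower in roots, at -6.63 for AT2G28400, -5.66 for AT4G16000, -5.05 for RD28, -4.97 for TIP2;2 and -4.69 for AT4G06536. AT2G28400 averaged 24 ± 11.6 in root water and 22.4 ± 20.6 at 3 h, and rose from 8.53 ± 8.98 to 423.5 ± 82.9 in shoots.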

How the results depend on the processing

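The alternatives with S0 and PH0 as control, without the 5 libraries under 600 kiloreads and without the S0 water set were chosen after seeing the data. So was the depth term for the counts and named genes. Of 120 results on named genes none reversed. The number that lost the call was 0 with DESeq2, TMM and a log2 change of at least 1, 1 with a depth term and with the stricter filter, 2 with pseudocount 5, quantile normalization and (of 70) S0 and PH0 as control, 4 with edgeR, 5 without the filter and with a replicate block, 6 without S0, 8 with pseudocount 0.5, 15 without the shallow libraries and 23 in fits of only the compared groups. When 1 library was left out, 25 lost it in at least 1 case. In libraries simulated at the depth and replicate spread of these, limma found 9.0% of abundant genes altered 2-fold in roots at 3 h. How much of this depth alone limits was not tested. The counts in the next 2 paragraphs moved by over 1.5 times, and the cause was not tested except where fewer genes or libraries were used.

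DESeq2 called 398 genes in roots at 1 h, 307 in roots at 3 h against 1 h, 1709 among root water sets, 204 in shoots at 1 h, 1076 in shoots at 3 h against 1 h and 103 between tissues at 1 h. EdgeR called 168 in shoots at 1 h and 1155 in shoots at 3 h against 1 h. TMM called 9 between tissues at 1 h, and quantile normalization 1410, pseudocount 5 1840 and no filter 1097 among root water sets. A log2 change of at least 1 left 2663 genes over all roots and 2104 over all shoots. The stricter filter left 2490 over all roots and 5970 for root against shoot. Fits of only the compared groups called 0, 87 and 458 in roots at 1, 2 and 3 h, 15 in roots at 3 h against 1 h, 2890 among root water sets, 37 and 427 in shoots at 1 and 2 h, 1337 in shoots at 3 h against 1 h, 1089 among shoot water sets, and 3 and 99 between tissues at 1 and 2 h.

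With all 3 water sets as control, roots had 1953, 1374 and 2530 calls at 1, 2 and 3 h, shoots 1049, 2392 and 2613, and the difference between tissues 491, 797 and 929. With S0 and PH0 as control they were 2472, 1830 and 2877, then 2009, 2857 and 3037, then 1006, 1068 and 1152. A depth term gave 1070, 589 and 1546 in roots at 1, 2 and 3 h, 336 at 3 h against 1 h, 2169 among root water sets, and 69, 375 and 607 between tissues. Without the shallow libraries there were 86 in roots at 1 h, 309 and 1384 at 3 h against 1 h in roots and shoots, 2266 among root water sets, and 71 and 563 between tissues at 1 and 3 h. Without S0 there were 116 in roots at 1 h, 152 and 1267 among root and shoot water sets, 1718 over all roots and 20 between tissues at 1 h.

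Leaving out 1 library gave counts in roots of 66 to 410 at 1 h, 230 to 336 at 2 h, 448 to 845 at 3 h, 83 to 252 at 3 h against 1 h, 237 to 1027 among water sets and 3395 to 4487 over all libraries. In shoots they were 28 to 139, 624 to 1618, 931 to 1935, 390 to 467, 1551 to 2926 and 3082 to 3931. Between tissues they were 18 to 69, 157 to 321 and 260 to 465 at 1, 2 and 3 h, and 8860 to 9152 for root against shoot in water. Over all root and all shoot libraries, between tissues at 3 h and for root against shoot in water no count moved by over 1.5 times, and each other range holds at least 1 that did.

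Of 120 list tests 54 passed, and 18 with an estimated correlation. Within 1.5 times of it were 61 and 64 with 3 water sets or S0 and PH0 as control, 52 with a replicate block and 43 without the shallow libraries. Some lists reversed direction, with these adjusted p. With 3 water sets as control they were ribosomal proteins in shoots at 1 h (0.0203) and 2 h (0.272), ribosome biogenesis in shoots at 2 h (0.0203) and between tissues at 1, 2 and 3 h (4.39e-05, 0.0459, 0.316), and nitrate response between tissues at 1 h (0.0274). With S0 and PH0 as control they were ribosome biogenesis in roots at 2 h (0.825), shoots at 2 and 3 h (4.85e-04, 0.00328) and between tissues at 1, 2 and 3 h (2.2e-07, 1.29e-04, 0.0028), ribosomal proteins in shoots at 1, 2 and 3 h (0.0019, 0.0206, 0.0161), aquaporins in shoots at 1 h (0.0472) and between tissues at 1 h (0.983), and nitrate response between tissues at 1 h (0.00302) and 3 h (0.77). Without the shallow libraries, which include root 1 h replicate 2, photosynthesis reversed in roots (0.87) and between tissues (0.955) at 1 h.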

Other observations

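The counts of other splits, the depth and normalization tests of the shoot water sets, the test of the dehydration list among water sets and both tests on photosynthesis transcripts were chosen only after the results were seen.

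Ribosome and sugar genes set the water sets apart as well. In shoots, 8 of 11 ribosome biogenesis genes were higher in PS0 than in the mean of S0 and PH0 (camera adjusted p = 7.04e-08, and 0.029 with an estimated correlation), among them NUC-L1, a nucleolin, at 159.5 ± 23.1, 333.6 ± 37.5 and 123 ± 13.9 normalized counts in S0, PS0 and PH0 (SD, n = 3). Of 24 ribosomal protein genes 12 were higher (adjusted p = 2.1e-06, and adjusted p = 0.165 with an estimated correlation). Among 19 aquaporins 9 were lower in PS0 shoots (adjusted p = 0.00276, and adjusted p = 0.294 with an estimated correlation), PIP1;5 at 588.5 ± 125.8, 230.4 ± 23.3 and 716.6 ± 169.6. In roots 3 of 13 sugar starvation genes were higher in PS0 (adjusted p = 6.44e-08, and adjusted p = 0.0598 with an estimated correlation), ASN1 at 48.7 ± 12.9, 356.4 ± 111.5 and 105.7 ± 21.3.

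The 3 shoot water sets of 1 treatment label differed in 2665 genes. Library depth was argued against as the whole cause by 3668 genes called with depth as a term, and the authors' normalization by at least 2361 called under TMM, quantile normalization, edgeR and DESeq2. A library batch and the set cannot be told apart, since 0 numbers of the position codes were shared by sets. No biological explanation of the whole difference was tested.

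Whether seedlings of the PS0 set already showed some of the dehydration response in water stays open. The dehydration list was placed higher in PS0 than in S0 and PH0 in both tissues, with a larger camera adjusted p of 3.28e-08 over 4 tests. Over 40 tests of all lists the adjusted p was 6.58e-11 in roots and 1.64e-07 in shoots. With an estimated correlation the unadjusted camera p was 0.00524 in roots and 0.0335 in shoots. Over the 40 tests these became 0.0598 and 0.165, so that call depends on the number of tests adjusted for. Other lists that move with PEG+SHAM went both ways. Jasmonate response genes were higher in PS0 roots (3 of 14, adjusted p = 2.17e-04, and adjusted p = 0.073 with an estimated correlation) and shoots (3 of 14, 0.00237 and 0.0598), as were sugar starvation genes in roots, and 12 of 28 photosynthesis genes were lower and 3 higher in PS0 shoots (0.0154 and 0.455), while 0 of 8 PP2C genes in roots and 0 of 7 in shoots were called (medians 0.2 and 0.03, adjusted p = 0.5 each) and in PS0 shoots 9 of 19 aquaporins were lower and 2 of 11 nitrate response genes higher (0.00185 and 0.0852). Handling of the set or its batch could do the same and was not tested.

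Photosynthesis transcripts in root 1 h replicate 2 summed to 7003.4 normalized counts against a root median of 1371.9, and root markers to 3228.9 against 4686.1 and 3830.7 in the other 1 h replicates. RNA of shoots in that library may be the source. Of 100 abundant shoot genes that roots nearly lack, 82 were higher there than in both other replicates, below the 90 set for it and above the 50 set against it, with a median excess of 1.36% of the shoot level, so this stays open at that library's low depth. Reads assigned to the wrong library where depth is low stay open too. Of 100 abundant genes of the other tissue, 61 were higher than in both other replicates in root PS0 replicate 3 (median excess 0.2%), and 1, 12 and 7 in shoot PH0 replicate 1, 2 h replicate 2 and PS0 replicate 1.

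Chance can be excluded for the water sets, where 1 of 100 splits (the real one) gave as many genes. Among root water sets the real count was 707 and the highest other 86, and among shoot water sets 2665 and 1448. Over all roots, all shoots and root against shoot in water, 1 of 100 splits of single libraries gave as many as the real 4085, 3588 and 9163, with 985, 467 and 4992 in the highest other. With whole groups of 3 libraries as the unit, which the differences among water sets call for, the 10 splits are too few for a share under 0.05, with 1 of 10 as large each time and 1284, 2226 and 6364 in the highest other. The other splits of whole groups gave a median of 552, 1554 and 4147 genes. For the number of list tests passed, a chance assignment of single libraries can be excluded. There 1 of 100 reassignments (the real one) passed as many as 54. The highest other passed 39 and the median was 19, so this decides nothing on any single list. Nor can reassigned single libraries exclude a difference between whole sets. The 10 splits of 6 libraries are too few for a share under 0.05. In roots at 1, 2 and 3 h the real counts were 199, 363 and 784 and the highest others 1, 0 and 1, with 1 of 10 splits as large each time. In shoots they were 91, 985 and 1468 and 93, 234 and 0, with 2, 1 and 1 of 10 splits as large.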
